A study of Mus musculus with 6 samples.

How the data were processed

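Total RNA of E12.5 dorsal cortex from 3 wild-type and 3 Emx1-Cre miR-7 sponge mice was sequenced, per the labels. Groups and animal numbers were taken from the sample titles, which name separate animals. The authors deposited a table of RPKM values (read numbers scaled to gene length and library depth), per the file headers, with 1 row for each of 37681 mouse genes and 1 column per animal, and no column of other samples. The authors also deposited a coverage signal track for each library, per the file headers, with the number of reads over each interval and no scaling to depth. Genome build mm9 is named in the submitters' processing notes. The aligner, the counting program and the annotation release are not given in the sources used here. Whether counting used strand is also not given, so overlapping and antisense genes could share reads.

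RPKM values are not counts, and a table of counts was not used here, so no count test was the main test. The values were whole multiples of what 1 read is worth in a gene and library, to within the printed decimals. From these steps a unique whole number of reads was recovered for 95.3% of genes, an ambiguous one for 4.59%, and none for 46 genes. Among the 13724 genes with a mean of at least 1 RPKM, 87.1% were unique and 12.6% ambiguous, and all 46 lay there. No value was 0, and 12102 genes stood at the lowest step in all 6 libraries, so that a gene without reads could not be told from one with 1 read. The reads recovered in uniquely resolved genes were between 18680768 and 24895608 per library. The 10 most abundant genes took between 6.26% and 8.32% of the RPKM total of a library. The track of sponge animal 2 ran without gaps from position 3 of chromosome 1, held 20 chromosomes where the others held 22, and was only described.

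Genes with a mean of at least 1 RPKM were kept. The test was limma 3.58.1 (R 4.3.3, eBayes with trend) on log2(RPKM + 0.5), two-sided, with group as the only term, Benjamini-Hochberg adjustment over the 13724 genes and a threshold of 0.05. Fold changes are on the log2(RPKM + 0.5) scale, which understates those of low genes. Before the data were examined, 29 gene lists were written, and 24 with at least 5 kept members were tested with camera (preset correlation 0.01) and adjusted over the 24 lists; camera with an estimated correlation and fry were alternatives. The other 5 lists had fewer than 5 kept members and are reported gene by gene. They were the sex-linked genes, the miR-7 host and driver genes, the 2 genes known from the study, diencephalic and caudal brain genes (3 kept) and epidermal and muscle genes (4 kept). Of 539 listed entries 536 were matched to the table, by symbol or by the Ensembl identifier of the symbol in GENCODE M21. Named genes were the 10 largest changes in each direction among genes past the threshold with groups that did not overlap, the up to 3 members of each list with the smallest p, and 11 genes fixed beforehand. Other named genes were chosen after their values were seen, and some single genes are not reported here.

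Matches to miR-7 seed sites were searched in the longest annotated 3′ UTR of each gene in GENCODE M21, joined by gene identifier. That annotation is of GRCm38, not of mm9, so no coordinates are given. Of the kept genes 2801 had no annotated 3′ UTR under their identifier and count as not searched.

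The procedure was tested on simulated data for the sponge comparison, with reads drawn at the real means and depths and a dispersion of 0.01. In 20 draws, each testing between 13509 and 13544 genes, the test recovered on average 54.9% of 100 genes changed 1.5-fold and 94.3% of 100 genes changed 2-fold. On average 8.48% of the calls were unchanged genes, above the nominal 5%, with a range from 4.93% to 11.3%. The count of changed genes should therefore be read with a higher error rate than its threshold states.

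Alternatives fixed before the data were examined were pseudocounts of 0.1 and 1, no filter and a mean of at least 5 RPKM, quantile and median-of-ratios scaling, a replicate block, eBayes without trend and robust, a 1.5-fold minimum, the other set tests and seed definitions, and leaving out each library. Chosen after seeing the data were a male indicator (Ddx3y above 1 RPKM) and limma voom on the recovered reads, ambiguous ones included. Counting reads over exons was not done, since no annotation of mm9 was used here. Figures were drawn with matplotlib 3.10.9.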

Results

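RNA from the dorsal cortex of 6 mouse embryos at E12.5 was compared between 3 wild-type animals and 3 animals carrying Emx1-Cre and a miR-7 sponge. A sponge is a transgenic transcript with binding sites for a microRNA, which it occupies in place of the microRNA's own targets. Emx1-Cre is a recombinase driven in the progenitors of the dorsal forebrain. The comparison addressed how mRNA levels in the cortex differ between sponge and wild-type animals. The sponge transcript is not an endogenous gene and could not be read from the gene values. How far miR-7 was blocked was therefore not measured here. The reads that could be recovered from the deposited values numbered 20265437, 21123001 and 20492071 in wild-type animals 1 to 3 and 18680768, 24895608 and 19856322 in sponge animals 1 to 3. Of 37681 genes 13724 reached a mean of 1 RPKM. A gene near 1 RPKM rested on a median of 111 to 173 reads per library. The correlation of log2 values across genes, which are not independent replicates, lay between 0.979 and 0.994 for the 6 pairs of libraries within a group and between 0.975 and 0.985 for the 9 pairs between groups.

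The groups differed in sex. Xist, the RNA that coats the inactive X chromosome of females, stood at 126, 112 and 74.1 RPKM in wild-type animals 1 to 3 and at 69.6 RPKM in sponge animal 2. It stood at 0.216 and 0.322 RPKM in sponge animals 1 and 3. The Y-linked gene Kdm5d stood at 6.44 and 6.63 RPKM in sponge animals 1 and 3, at 0.0404 RPKM in sponge animal 2 and at no more than 0.00342 RPKM in the wild-type animals. Sex therefore could not be separated from genotype except through sponge animal 2. The library names carried 1 lane tag for the wild-type libraries, another for sponge animals 2 and 3 and none for sponge animal 1. Lane and genotype could therefore not be told apart either. No group carried Emx1-Cre without the sponge, so that a difference between the groups could come from either of them.

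The driver, the miR-7 host gene and the pathway genes chosen for the sponge came first. Emx1, the cortical transcription factor gene whose regulatory sequence drives the Cre, fell from 63.4 ± 2.9 RPKM in wild-type animals to 44.2 ± 3.5 RPKM in sponge animals (SD, n = 3 each), a log2 fold change of -0.52 ± 0.08 (SE; limma, adjusted p = 0.020). Hnrnpk, an RNA-binding protein gene that hosts a miR-7 precursor, was at 35.3 ± 1.2 and 32.9 ± 0.18 RPKM and did not pass the test (limma, adjusted p = 0.37). Cdkn1a, the cell cycle inhibitor p21, rose from 10.8 ± 1.2 to 21.5 ± 1.7 RPKM (log2 fold change 0.96 ± 0.10, limma, adjusted p = 0.0057). Ak1, an adenylate kinase gene, rose from 1.95 ± 0.12 to 3.19 ± 0.073 RPKM (0.59 ± 0.07, limma, adjusted p = 0.0086). Ak1 and Cdkn1a were known from the study itself, so that their rise is not independent evidence. Ccng1 and Trp53inp1, both transcribed by p53, rose by 1.27 and 0.65 on the log2 scale, whereas Mdm2 (0.06) and Bax (0.30) did not pass. Pax6 (-0.21), Eomes (-0.41) and Tbr1 (-0.13), transcription factor genes of radial glia, intermediate progenitors and early neurons, did not pass either. Over the alternative settings they ranged from -0.46 to -0.088 (Pax6), -0.84 to -0.20 (Eomes) and -0.71 to 0.17 (Tbr1). Pax6 and Eomes passed as lower in 1 of these settings, the male indicator, where the genotype effect rests on sponge animal 2 alone. Of these 11 genes 5 were past the threshold, 2 without wild-type animal 2 and 3 without wild-type animal 3. The calls of 3 of them were lost in some fits with 1 library left out, each with fewer samples. Their log2 fold changes in those fits stayed between -0.58 and -0.48 (Emx1), 0.59 and 0.72 (Trp53inp1) and 0.56 and 0.62 (Ak1). Emx1 was lost without wild-type animal 1, 2 or 3 or sponge animal 1 (limma, adjusted p = 0.062, 0.10, 0.069 and 0.055). Trp53inp1 was lost without wild-type animal 2 or 3 or sponge animal 3 (0.094, 0.070 and 0.061) and with a male indicator (0.055), and Ak1 without wild-type animal 2 (0.053). Cdkn1a and Ccng1 passed in all 6 fits with 1 library left out.

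**Figure D1:**
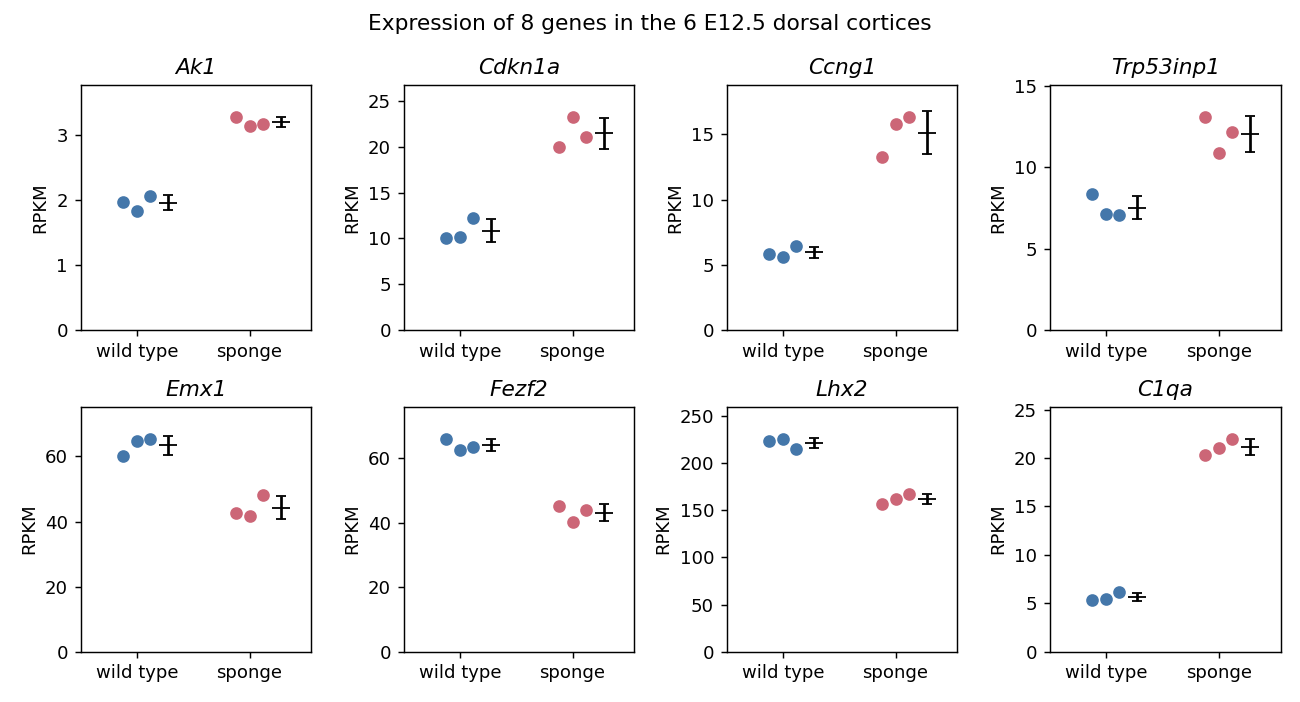
RPKM (vertical axis, from 0) of 8 genes in the 3 wild-type (blue) and 3 sponge (red) animals; each point is an animal, and the black mark beside them is the group mean with its SD (n = 3). All 8 genes have groups that do not overlap, with Emx1, Fezf2 and Lhx2 lower and the other 5 higher in sponge animals.

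Across the 13724 genes, 403 were past the threshold (limma, Benjamini-Hochberg adjusted), of which 327 rose and 76 fell in sponge animals. Of the genes that rose, 53 did so at least 2-fold, against 1 of those that fell. The groups did not overlap for 27.0% of the genes, where chance gives 10%. Of the 10 largest rises 8 belonged to genes of microglia and macrophages: Fcrls (2.03 ± 0.07 on the log2 scale), Mpeg1 (1.86 ± 0.06), Tyrobp (1.86 ± 0.07), Lyz2 (1.83 ± 0.17), the complement genes C1qa (1.82 ± 0.07) and C1qb (1.81 ± 0.08), Ctss (1.69 ± 0.09) and the fractalkine receptor gene Cx3cr1 (1.60 ± 0.09). The other 2 were Eda2r (1.68 ± 0.10), a p53 target, and Apoe (1.65 ± 0.11), a lipid carrier. The 10 largest falls were smaller. They included the Notch effector Hey1 (-0.70 ± 0.09), the X-linked gene Mid1 (-0.68 ± 0.10), the ammonia transporter gene Rhcg (-0.64 ± 0.12), G530011O06Rik (-0.92 ± 0.16) and the unnamed transcripts Gm17592 (-1.01 ± 0.16), Gm15726 (-0.89 ± 0.10), Gm15247 (-0.87 ± 0.06), Gm9009 (-0.69 ± 0.13), AL603836.1 (-0.65 ± 0.11) and Gm11266 (-0.62 ± 0.10). With a male indicator in the model, a setting chosen after the data were seen in which the genotype effect rests on sponge animal 2 alone, 475 genes rose and 400 fell. Without wild-type animals 1 to 3 in turn 120, 90 and 191 genes were called, and without sponge animals 1 to 3 in turn 249, 274 and 248. The genes that fell, 76 with all libraries, then numbered 6, 3 and 23 without wild-type animals 1 to 3 and 48, 53 and 21 without sponge animals 1 to 3. Of the 10 largest falls Gm15247 was past the threshold in all 6 of these fits and Rhcg in none.

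Genes of microglia and macrophages and of the meninges and mesenchyme were higher in sponge animals. Of 14 measured microglia and macrophage genes 11 rose and none fell (14 adjusted over the list alone), with a median of 2.21-fold. C1qc rose from 3.72 to 11.4 RPKM and Csf1r, the receptor that microglia need to survive, from 2.17 to 4.80 RPKM. Of 19 meningeal and mesenchymal genes 10 rose (16 adjusted over the list alone), with a median of 1.60-fold. Among them were the collagen gene Col3a1 (31.3 to 58.3 RPKM), the growth factor receptor gene Pdgfra (3.38 to 7.48 RPKM) and the transcription factor gene Foxc1 (a rise of 0.66 on the log2 scale). Both lists passed the set test (camera, adjusted p = 3.8e-25 and 8.4e-18) and passed with an estimated correlation (adjusted p = 0.033 and 0.022). Of 18 cortical hem and choroid plexus genes 3 rose, the transcription factor genes Otx2 and Msx1 and the water channel gene Aqp1 (11 adjusted over the list alone). The list was called by camera (adjusted p = 8.1e-11), but with adjusted p = 0.21 with an estimated correlation. Fewer of the mesenchymal genes rose without wild-type animal 1 or 2 (6 and 5), and without wild-type animal 1 or 2 or sponge animal 1 only 1, 0 and 1 of the hem and choroid plexus genes. Of the latter 1 rose without a filter and 6 with the male indicator, where the list median was 0.86 against 0.50. Of 18 endothelial and pericyte genes only Pdgfrb rose (also 1 adjusted over the list alone). It was past the threshold in none of the 6 fits with 1 library left out. The list median was 0.27 on the log2 scale (camera, adjusted p = 2.4e-06; adjusted p = 0.33 with an estimated correlation). With 1 library left out that median lay between 0.16 and 0.33. Of 11 erythroid genes none was past the threshold (limma, 0 also at an unadjusted p under 0.05 and 0 adjusted over the list alone; camera, adjusted p = 0.82). With the male indicator that list was called as higher (camera, adjusted p = 0.024). Of 11 Cajal-Retzius cell genes none was past the threshold (limma, 3 higher at an unadjusted p under 0.05, 0 adjusted over the list alone), with a list median of 0.30 (camera, adjusted p = 0.019; adjusted p = 0.21 with an estimated correlation). That call was lost without wild-type animal 2 or sponge animal 1 (camera, adjusted p = 0.051 and 0.075) and with the male indicator (0.19), where the list median was 0.02 and 1 member rose.

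Of 13 measured genes of a list of retinoid, FGF and Hedgehog signalling 6 rose and none fell (10 rose and 1 fell adjusted over the list alone). Fgf17, a growth factor of the rostral forebrain, rose from 14.2 to 24.8 RPKM. The FGF feedback genes Dusp6 and Spry2 rose from 8.89 to 12.2 RPKM and from 7.29 to 11.6 RPKM. The retinoic acid receptor gene Rarb rose from 1.44 to 2.69 RPKM and the retinoid-binding protein gene Crabp1 from 15.4 to 27.0 RPKM, while Crabp2 had a log2 fold change of -0.44 and did not pass over all genes. The list passed the set test (camera, adjusted p = 1.3e-07) and passed with an estimated correlation (adjusted p = 0.033). The Hedgehog genes of the list did not pass, with log2 fold changes of 0.59 for Ptch1, -0.16 for Gli2 and -0.13 for Gli3. Without wild-type animals 1 to 3 in turn 2, 1 and 2 members rose, of 14 that were measured in each of these fits. Without sponge animal 1, 3 of 13 rose, and without a filter 3 of 20.

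Genes transcribed by p53 were higher in sponge animals. Of 31 measured members 10 rose, 1 fell and 20 did not pass (15 rose and 1 fell adjusted over the list alone). Eda2r rose from 0.619 ± 0.071 to 3.10 ± 0.40 RPKM, Ccng1 from 5.96 ± 0.43 to 15.1 ± 1.6 RPKM and the stress gene Sesn2 from 5.08 ± 0.24 to 12.1 ± 1.4 RPKM (SD, n = 3 each). The member that fell was Rprm, a cell cycle inhibitor gene, by 0.42 on the log2 scale. It was past the threshold in none of the 6 fits with 1 library left out. The list median was 0.19 and its mean 0.38, and it passed the set test (camera, adjusted p = 2.0e-09) and passed with an estimated correlation (adjusted p = 0.046). Over the 20 members with a mean of at least 5 RPKM the median was 0.08 and 5 rose. In the list of cell death genes, 3 of 23 rose (5 adjusted over the list alone), all 3 of them p53 targets as well: Pmaip1 (1.39 ± 0.15), Bbc3 (0.65 ± 0.12) and Tnfrsf10b (0.57 ± 0.10). The list was called by camera (adjusted p = 0.0024), but with adjusted p = 0.19 with an estimated correlation. Without wild-type animals 1 to 3 in turn 6, 5 and 5 of the p53 targets rose, and 5 without sponge animal 3, while the list was past the threshold in all 6 such fits. Of the cell death genes 1 rose in each fit without a wild-type animal and in the fit without sponge animal 3, 1 also without a filter or with quantile normalization, and none of the 12 with a mean of at least 5 RPKM.

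Single genes of cortical progenitors and neurons fell. Of 20 radial glia genes 4 fell and none rose (6 fell and 2 rose adjusted over the list alone). They were the transcription factor genes Lhx2 (221 to 162 RPKM) and Emx2 (58.1 to 44.4 RPKM), the inhibitor of differentiation gene Id4 (343 to 243 RPKM) and the FGF receptor gene Fgfr3 (14.5 to 11.0 RPKM). Of 14 intermediate progenitor genes only Nhlh1 fell, from 44.2 to 29.9 RPKM (6 fell adjusted over the list alone). Nhlh1 was past the threshold in 2 of the 6 fits with 1 library left out, those without sponge animal 1 or 2, and with the male indicator 6 of the 14 genes fell, with a list median of -0.50 against -0.25. Of 22 early neuron genes only Fezf2, a transcription factor of deep-layer neurons, fell, from 64.2 to 43.1 RPKM (1 adjusted over the list alone). Fezf2 did not pass without wild-type animal 1 or 2 (limma, adjusted p = 0.052 and 0.055). The first 2 lists were called by camera (adjusted p = 0.0052 and 0.0037), but had adjusted p = 0.22 and 0.33 with an estimated correlation. The neuron list was not called (adjusted p = 0.099). No single gene of the 24 G1/S genes or of the 24 G2/M genes was past the threshold (limma, 0 adjusted over the list alone in both, 11 and 9 lower at an unadjusted p under 0.05), yet 23 of the former and 24 of the latter were lower, with medians of -0.14 and -0.15 on the log2 scale. With the male indicator 1 and 2 of them fell, and with voom 1 of the G1/S genes. Both lists were called by camera (adjusted p = 1.2e-05 and 1.5e-05), with adjusted p = 0.33 and 0.28 with an estimated correlation. The median of 13 housekeeping genes, 9 of them lower, was -0.125 and thus close to those of both lists. With quantile normalization the G1/S, G2/M and housekeeping medians were -0.103, -0.0977 and -0.0226. Of 21 Notch pathway genes Hey1 fell (2 adjusted over the list alone), and the list was not called (camera, adjusted p = 0.064), but was without wild-type animal 3 or sponge animal 1 (0.046 and 0.036), in 4 other settings (0.0043 to 0.050) and by fry (adjusted p = 0.0013). Hey1 did not pass without wild-type animal 2 or 3 (limma, adjusted p = 0.069 and 0.052), and with the male indicator 2 genes of the list fell and 1 rose. Without wild-type animals 1 to 3 in turn 0, 0 and 1 of the radial glia genes fell, and without sponge animals 1 to 3 in turn 1, 2 and 1. None fell without a filter, 1 with quantile normalization and 2 with median-of-ratios scaling. The neuron list was called as lower without wild-type animal 2 or sponge animal 1 (camera, adjusted p = 0.019 and 8.8e-05), with the male indicator (7.2e-06), without a filter (0.012) and with median-of-ratios scaling (0.047). Its median of -0.13 became -0.55 with the male indicator and 0.07 without sponge animal 2. Genes of the ventral telencephalon, which lies beside the dissected tissue, varied between animals. Dlx2, named after its values were seen, stood at 11.0, 0.780 and 4.14 RPKM in sponge animals 1 to 3 and at 1.64, 0.341 and 0.412 RPKM in wild-type animals 1 to 3. Of the 8 measured members of that list none rose (limma, 4 higher at an unadjusted p under 0.05, 2 adjusted over the list alone). The list median was 0.66. The list was called as higher (camera, adjusted p = 0.015; adjusted p = 0.36 with an estimated correlation) and was not called without sponge animal 1 (camera, adjusted p = 0.37) or with the male indicator (0.64). With 1 library left out its median lay between 0.41, without sponge animal 1, and 1.30, without sponge animal 2, over 6 to 10 measured members.

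**Figure D2:**
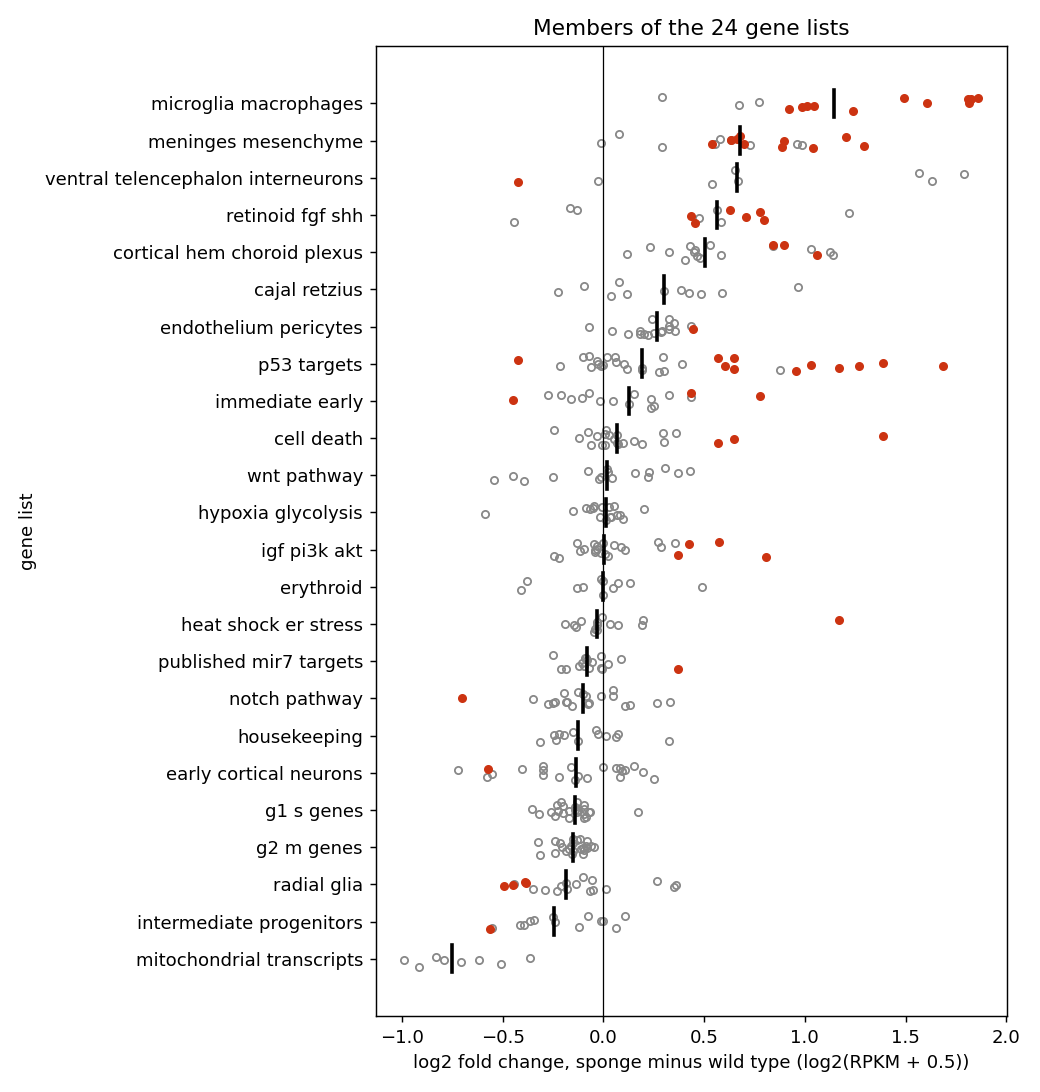
Log2 fold change (horizontal axis, sponge minus wild type, on log2(RPKM + 0.5)) of each measured member of the 24 gene lists (vertical axis, ordered by median). Filled red points are genes past the threshold (limma, adjusted p under 0.05), open points are the others and black lines are list medians; the microglia list has the highest median, 1.14, and the mitochondrial list the lowest, -0.75.

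The remaining lists moved less or varied between libraries. Transcripts of the mitochondrial genome had a list median of -0.75, with no member of 8 past the threshold (limma, 0 also at an unadjusted p under 0.05 and 0 adjusted over the list alone). The sponge animals differed among themselves, and mt-Nd1 stood at 2403, 761 and 1469 RPKM in sponge animals 1 to 3 and at 2345, 2361 and 2516 RPKM in wild-type animals 1 to 3. The list was called by camera (adjusted p = 0.012), with adjusted p = 0.47 with an estimated correlation, and was not called without sponge animal 2 (camera, adjusted p = 0.065). The list median was -0.33 without sponge animal 2 and -1.16 without sponge animal 1. With the male indicator it was -1.60 and 7 of the 8 members fell. Of 17 immediate early genes Dusp6 and Atf3 rose and Jun fell (7 rose and 2 fell adjusted over the list alone; camera, adjusted p = 0.035; adjusted p = 0.21 with an estimated correlation), a call lost without wild-type animal 2 or sponge animal 1 or 3 (camera, adjusted p = 0.065, 0.081 and 0.090), with the male indicator (0.24) and in 4 other settings (0.055 to 0.51). These 3 genes did not pass without wild-type animal 1 or 2. Dusp6 passed in the other 4 fits with 1 library left out, Jun in 2 of the 6 and Atf3 in 1. Of 24 genes of insulin-like growth factor and PI3K signalling 4 rose, namely Igf1, Igf2, Irs2 and Foxo1 (6 adjusted over the list alone), and the list was not called (camera, adjusted p = 0.055), but was without wild-type animal 1 or 2 or sponge animal 3 (0.015, 0.019 and 0.035) and with 4 other filters or scalings (0.034 to 0.047). Without wild-type animals 1 to 3 in turn 1, 0 and 1 of its members rose, and 2 without each sponge animal, without a filter or with the male indicator. Sesn2 alone rose among 15 heat shock and endoplasmic reticulum stress genes (1 adjusted over the list alone; camera, adjusted p = 0.77). No gene of the 16 Wnt pathway, 17 hypoxia and glycolysis or 13 housekeeping genes was past the threshold (limma, 0 adjusted over each list alone, with 4, 1 and 4 at an unadjusted p under 0.05), and these lists were not called (camera, adjusted p = 0.55, 0.82 and 0.17), except the hypoxia list without sponge animal 1 (0.015) and the housekeeping list without a filter (0.030) and by fry (0.045). Of the Wnt genes 2 rose and 3 fell with the male indicator, 1 of 21 rose without a filter and 1 fell without sponge animal 2. Of the measured genes of 2 lists too short to test, none was past the threshold. These were Lhx9, Irx3 and Irx5 of the diencephalon and caudal brain (log2 fold changes of -0.23, 0.89 and 0.58) and Krt8, Krt18, Epcam and Grhl3 of the epidermis (0.54, 0.62, 0.28 and 0.02).

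**Figure D3:**
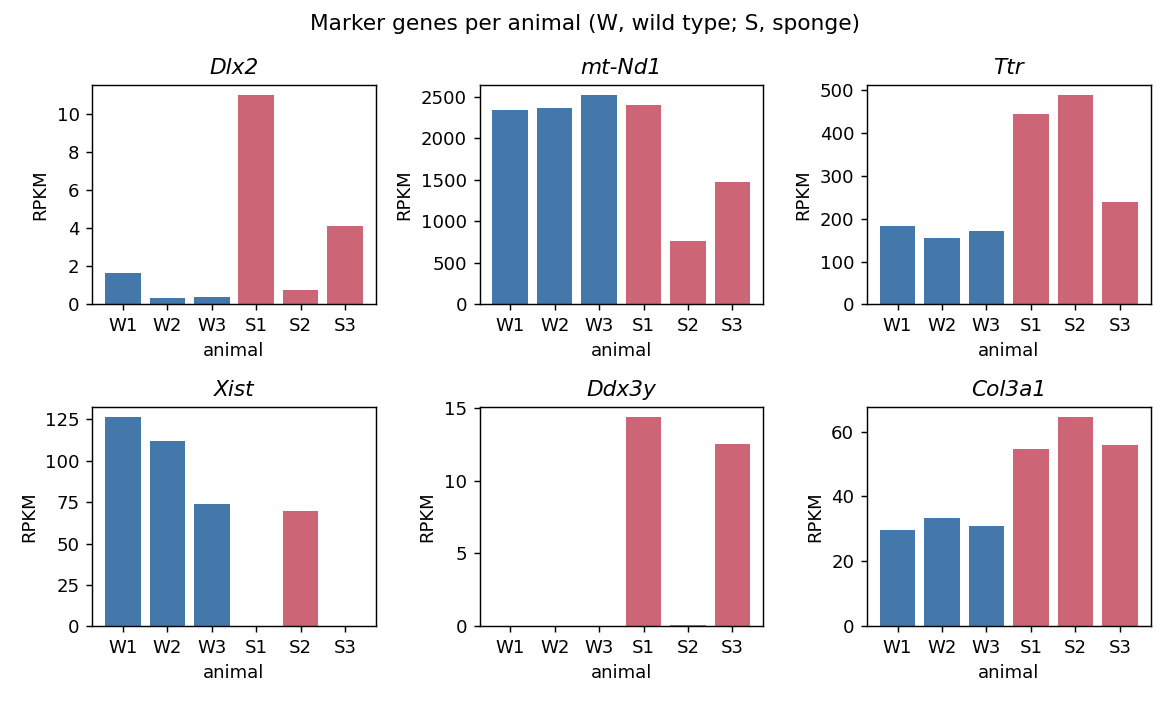
RPKM (vertical axes, from 0) of 6 marker genes in each animal (horizontal axes; W, wild type, blue; S, sponge, red). Ddx3y is above 1 RPKM in sponge animals 1 and 3 alone, where Xist is at 0.216 and 0.322 RPKM, Dlx2 is highest in sponge animal 1 (11.0 RPKM), mt-Nd1 is lowest in sponge animal 2 (761 RPKM), and Ttr and Col3a1 are higher in each sponge animal than in any wild-type animal.

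Transcripts with a match to the miR-7 seed, the bases by which a microRNA finds its targets, did not differ detectably from the others. Of 10923 genes with an annotated 3′ UTR, 2896 had at least 1 match to GTCTTCC or TCTTCCA and 8027 had none. The median log2 fold change was -0.022 with and -0.030 without a match, a difference of 0.0079 (camera, p = 0.66; p = 0.80 with an estimated correlation). For GTCTTCC alone the difference was 0.0074, and 84 of 140 heptamers of the same base composition gave one at least as high, over a range from -0.019 to 0.024. A match was present in 28.1% of the searched genes that rose, 26.3% of those that fell and 26.5% of all genes searched (Fisher's exact test, two-sided, p = 0.55 for those that rose). Of 17 measured published targets of miR-7 only Irs2, whose 3′ UTR holds 2 of the GTCTTCC matches, rose, from 5.46 to 7.22 RPKM (also 1 adjusted over the list alone). Irs2 was past the threshold in none of the 6 fits with 1 library left out (limma, adjusted p from 0.061 to 0.14). The list was not called (camera, adjusted p = 0.15). The 3′ UTR of Ak1 holds 1 match and that of Cdkn1a none. The difference changed sign with a background matched on UTR length (-0.0043), with the male indicator (-0.027), without wild-type animal 3 (-0.014) and without sponge animal 1 (-0.012).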

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

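All tests in this part were chosen after the values were seen. The coverage tracks, which no comparison above used, held Y chromosome signal in 2 of the sponge libraries above the level of the wild-type libraries. Of every 1000000 aligned bases the Y chromosome took 187.5 in sponge animal 1 and 184.6 in sponge animal 3, against 1.33, 0.788 and 0.807 in wild-type animals 1 to 3. The track of sponge animal 2 was malformed and gave no such value, but its Ddx3y level was 0.0584 RPKM.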

How the results depend on the processing

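The male indicator and limma voom were chosen after seeing the data; the other settings were fixed before. The 403 changed genes became 174 with a mean of at least 5 RPKM, where 7690 genes were tested, 219 with a 1.5-fold minimum, which adds a condition, and 875 with the male indicator, of which 275 were among the 403 and 54.3% rose instead of 81.1%, and the cause was not tested. Between 343 and 591 genes were called in the other settings with all 6 libraries apart from the block, and 402 without a filter, of which 211 were shared. Without 1 library the count was 90 to 274, with fewer samples in each fit: 120, 90 and 191 without wild-type animals 1 to 3, and 249, 274 and 248 without sponge animals 1 to 3. With a replicate block 210 genes were called, 182 of them shared. The block called 0 genes of the radial glia list (4 without the block), 3 of the retinoid, FGF and Hedgehog list (6) and 1 of the insulin-like growth factor and PI3K list (4). The correlations of deviations of same-numbered animals were 0.32, 0.086 and 0.032, not all over 0.1. Wild-type animal 3 correlated best with sponge animal 2 (0.117), and wild-type animals 1 and 2 with the sponge animal of their own number. No label says that the numbers mark a litter or a day, and such correlations cannot exclude it. Of 24 lists 15 were called, 14 to 19 in the refits and 14 to 16 without 1 library, but 4 with an estimated correlation; fry called 12. Of the 11 fixed genes 5 were called, and 2 to 5 without 1 library (2 without wild-type animal 2, 3 without wild-type animal 3). The seed-match difference of 0.0079 reversed to -0.0043 with the length-matched background, to -0.027 with the male indicator and, without 1 library, ranged from -0.014 to 0.025; no setting brought it past the threshold, and the cause was not tested. Named genes kept their direction and their side of the threshold in 1383 of 1575 refits, and lists the sign of their median and their side in 386 of 454. The signs that turned were those of 3 gene refits and 18 list refits, the cause of which was not tested. With a mean of at least 5 RPKM the list medians were -0.013 (hypoxia), -0.0015 (insulin-like growth factor and PI3K) and -0.015 (immediate early). With the male indicator they were 0.37 (erythroid) and 0.041 (heat shock), and Hbb-bh1 was at 0.32. The erythroid median was 0.021 with median-of-ratios scaling and 0.015 with voom, and the heat shock median 0.015 without a filter. Without 1 library the medians ranged from -0.26 to 0.069 (early neurons), -0.24 to 0.21 (erythroid), -0.051 to 0.020 (heat shock), -0.058 to 0.090 (hypoxia) and -0.030 to 0.032 (insulin-like growth factor and PI3K), Hbb-bh1 from -0.73 to 0.043 and Tbr1 from -0.34 to 0.17. A test on deposited counts and an exon count on mm9 were not run. Genes near 1 RPKM rest on 111 to 173 reads, and lower genes on fewer.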

Other observations

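The tests in this part were chosen after the results were seen, except the mesenchyme and Dlx covariate fits, whose bounds were set before their results although the marker levels per animal were known. Genes of sterol and fatty acid synthesis were lower in sponge animals. This list was written after some of its members had been seen among the genes that fell. Of 28 measured members 27 were lower and 8 fell, with a median of -0.31 on the log2 scale. Insig1, a sensor of sterol supply, fell from 32.0 ± 0.55 to 23.6 ± 1.4 RPKM and Sqle, an early enzyme of sterol synthesis, from 18.0 ± 0.57 to 14.1 ± 0.34 RPKM (SD, n = 3 each). Scd2, Fdps, Dhcr7, Cyp51 and Sc4mol were among the others, and with the male indicator 6 of the list fell. The hypothesis that these genes fell together gave p = 0.0103 in camera with an estimated correlation, but the genes were picked from the same data, so that this test leaves it open.

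Some single genes stood out after their values were seen. The imprinted genes Igf2, H19 and Cdkn1c rose 1.49-fold, 1.53-fold and 1.71-fold, and the X-linked gene Gpc3 rose 1.92-fold. Mid1, G530011O06Rik, Gm15726 and Gm15247 were lower in each sponge animal than in any wild-type animal, sponge animal 2 included. The rule that picked them among the largest falls required this, so that the separation says nothing about sex. Eif2s3x, an X-linked gene, fell from 5.96 ± 0.32 to 4.01 ± 0.24 RPKM (SD, n = 3 each). Trp53 itself had a log2 fold change of -0.23 and was not past the threshold (limma, adjusted p = 0.18).

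The rise of p53 targets was weighed against tissue and sex. The 10 members that rose had a median log2 fold change of 0.99 with a median SE of 0.103. With a mesenchyme score as a covariate it was 0.755 with a median SE of 1.03 and no member called, so that mesenchymal tissue and genotype cannot be told apart for these genes. With the male indicator it was 1.08 and 8 of the 10 were past the threshold, but that fit rests on 1 female sponge library, and sex stays open. Effects of the sponge and of Emx1-Cre, candidate explanations, were not tested apart from these or from each other.

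The rise of microglia genes was weighed against a lower share of cortical cells and against macrophages from outside the brain tissue. A lower cortical share alone would raise other cell types alike, but the microglia list median lay 0.877 above that of the endothelium list. The permutation test (two-sided, p = 2e-05) took genes as replicates, so that it does not cover variation between animals. The endothelium list was picked after the values were seen, and the mesenchyme and the hem and choroid plexus medians were higher (0.68 and 0.50). With 1 library left out the microglia median lay between 1.103 and 1.186. The mesenchyme median then lay between 0.64 and 0.72 and the endothelium median between 0.16 and 0.33. These unequal rises argue against a lower cortical share as the whole cause. Macrophages from outside stay open: 5 border macrophage genes, 3 of them in the microglia list, had a median of 0.88, and 5 parenchymal microglia genes, 1 of them in that list, of 1.23, a difference of -0.346 with a spread of 0.37. Pf4 of the former stood at 10.7 and 18.8 RPKM in wild-type and sponge animals, and Cx3cr1 of the latter at 3.08 and 10.4 RPKM. In the opposite order, Lyz2 of the former rose by 1.83 on the log2 scale and Tmem119 of the latter by 0.79. A spread is here an approximate SE of a median over genes, which takes the genes as independent. A change in the number or state of microglia in sponge animals is a candidate explanation and was not tested.

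The fall of 6 cortical genes (Lhx2, Emx2, Id4, Fgfr3, Nhlh1 and Fezf2) was weighed against ventral tissue and dilution. With a Dlx score as a covariate their median was -0.488 (spread 0.091), against -0.47 (spread 0.042) without it. The median of the Dlx genes moved from 1.63 to 0.062, which was fixed in advance, since the score was their mean. The fall of the 6 cortical genes thus did not shrink with the Dlx score. These genes were picked as past the threshold in the same data, so that the fit does not exclude ventral tissue. The calls of 2 of the 6 ended in that fit, where the median SE was 0.078 instead of 0.074. Dilution by non-neural tissue stays open. The median over all 56 measured cortical members was -0.171 with a spread of 0.043, short of the bound set for dilution. With the Dlx score it was -0.42 and with the male indicator -0.44. The bound came from the 6 genes, picked as past the threshold, so that falling short of it cannot count against dilution. The spread takes genes as independent replicates and does not cover variation between animals. Sex, lane, Emx1-Cre and an effect of the sponge, each a possible explanation, were not separated.

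The 3 against 3 animals make 10 splits, too few for a share under 0.05. The real split gave 403 genes and the highest other 0 (limma, with 2575 and at most 1473 genes at an unadjusted p under 0.05), so that 1 of the 10 splits gave as many. It gave 15 lists and the highest other 11, with 1 of the 10 as many, and with an estimated correlation 4 lists and the highest other 0. The seed-match difference was 0.0079 in size and the highest other 0.043, with 7 of the 10 as large.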
